A study of Mus musculus with 2 samples.

How the data were processed

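Total RNA-seq was analysed for the urinary bladder of 2 newborn mice, pups of 1 pregnant female, with 1 library per pup. Per the labels' protocols, RNA was extracted with the Ambion mirVana method and a manual of a low-input SMARTer cDNA kit is linked, with 10 ng of RNA, a size range above 200 nt and spike-in RNAs added. The labels number the biological replicates, and pup 1 is replicate 1 and pup 2 is replicate 2. Both belong to 1 group, so the design holds no comparison between groups.

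The authors deposited 1 gene file and 1 transcript file per library in the layout that the RSEM estimator writes, on the mouse assembly mm10 with GENCODE M4 annotation per the text listing supplied with each sample. The aligner, the RSEM version and the strand setting are not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript, with multi-mapped reads divided among their targets by the authors' estimator, and they are not normalised. The deposited TPM values are scaled to a fixed sum over every entry of the file, spike-ins included, and the deposited FPKM values are per kilobase of effective length and sequencing depth. The deposited files also hold posterior mean versions of these values, the posterior SD of each count, and per transcript its percent of the gene. Effective lengths were 99 nt below the transcript length in all transcripts of at least 200 nt, so the TPM of short genes is raised. The division of reads among near-identical copies is an estimate, and a large posterior SD marks genes where it is uncertain. With strand use unknown, overlapping and antisense genes cannot be separated from their partners.

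Each gene file held 69691 entries: 43346 mouse genes, 97 spike-in entries (96 of them ERCC sequences) and 26248 entries with a numeric identifier, of which 99.8% had an effective length of 0. Of the mouse genes, 42462 were matched by identifier to symbols, biotypes and coordinates of GENCODE M21, which uses the same assembly. The other 884 held 0.124% of counts and kept their identifiers. Numeric-identifier and spike-in entries stayed out of the scaling and of gene counts. Depth was 43653931 expected counts in pup 1 and 32564563 in pup 2. A count of 0 allows up to 3 counts, which for a gene of 1 kb is 0.111 TPM in pup 1 and 0.139 TPM in pup 2. Intervals and these limits cover counting error only, since PCR copies of a molecule are not told apart.

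Expressed genes were those at 1 TPM or more in both pups. Levels are mean and SD of TPM over 2 pups. Between pups, rounded expected counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), and the log2 ratio of pup 2 over pup 1 was taken per gene, with a count of 0 set to 3. Ratios of TPM run lower than these by a median of 0.07 to 0.08 on the log2 scale. Per-gene intervals are exact binomial (Clopper-Pearson) intervals at 95%. Genes 2-fold apart needed a mean count of at least 100. With 1 library per animal the comparison leaves no residual degrees of freedom, so no test across animals was run. List medians used members with a mean count of at least 20 and were placed among 10000 random lists matched in 20 expression bins. The genes of a list vary together, so such a percentile describes these libraries and is no p-value. Leading transcripts were compared in genes with at least 10 TPM, and named for list genes with a mean count of at least 500. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

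The steps were tested on counts simulated from the means of these libraries, over 12724 genes. With a simulated coefficient of variation of 10%, 10.0% was recovered, 89 of 100 genes simulated at 2.5-fold and 100 of 100 at 4-fold were called 2-fold apart, and so was 1 of 12524 unchanged genes. The simulated spread was the same for all genes, whereas the pups had 17.7%, or 9.59% by the median absolute deviation. The share of unchanged genes called is therefore no error rate for the genes called between the pups.

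Before the data were examined, 41 gene lists, the settings, the alternatives and the rule for named genes were fixed. The rule takes the 10 highest nuclear protein-coding genes, up to 4 members per list by mean TPM, low members of the main bladder lists, the 8 largest differences in each direction among protein-coding genes with a mean count of at least 100, list members 2-fold apart, the Y-linked and X inactivation genes and 6 list genes with the largest shift of the leading transcript. Other genes named in the text, such as single list members given for contrast and Umod, Mylpf, Myl1, Myog, Mrc1, Bub1, Top2a, Ccna2, Ccnb2, Myh8, Ttr, Prox1, Ifit1, Ifit3, Crabp2, Epb42 and Chrm2, were chosen after their values were seen. The list member Ahsp was not found in the annotation used. A pair of gene lists added later, for sterol synthesis and inflammatory mediators, appears only in the closing observations. A version of the ribosomal protein list without kinases of ribosomal protein S6, also added later, is used in the results. Alternatives were other thresholds, DESeq2 1.42.0 size factors, scaling to the total count or to the spike-in total, TPM ratios with 1 or 0.1 added, posterior mean values, removal of an expression trend, and each pup alone. Signal tracks and alignments were not analysed here, and the spike-in concentrations were not used.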

Results

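The data described the RNA content of the newborn mouse bladder. Total RNA longer than 200 nt was sequenced from whole bladders of 2 pups of the inbred C57BL/6-derived strain B6NCrl, taken on postnatal day 0 from the litter of 1 pregnant female, with 1 library per pup made from 10 ng of RNA. Both samples form a single group, newborn bladder, in which each pup is a biological replicate (n = 2), and the labels give no sex. The gene file of pup 1 held 43653931 expected counts and that of pup 2 held 32564563, a ratio of 1.34. No treatment, age or tissue was contrasted, so the data answer 2 kinds of question: which genes the newborn bladder expressed and at what level, and how far 2 littermates differed. Levels below are mean TPM ± SD over the 2 pups, and with 1 library per pup no p-value across genes was computed.

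The newborn bladder expressed a broad set of genes dominated by contractile proteins and, in pup 2, by globins. At 1 TPM or more in both pups, 13834 genes were detected, of which 12568 were among the 21474 annotated protein-coding genes, 368 were long intergenic or antisense RNAs and 511 were pseudogenes. In single pups the totals were 14239 and 14372. The 10 nuclear protein-coding genes with the highest mean took 11.2% of TPM in pup 1 and 13.9% in pup 2. They were the smooth muscle actins Actg2 and Acta2, the cytoplasmic actin Actb, the tropomyosins Tpm1 and Tpm2, the myosin light chains Myl6 and Myl9, and the adult globins Hba-a1, Hba-a2 and Hbb-bs. All globins together took 2.17% of TPM in pup 1 and 5.90% in pup 2, and the genes of the mitochondrial chromosome took 4.86% and 4.46%. Ribosomal protein genes took 5.52% and 5.70%, and short structural RNAs took 2.86% and 3.73%. TPM divides by an effective length 99 nt shorter than the transcript, which raises short transcripts. By share of expected counts the mitochondrial genes were at 2.62% on average, the globins at 1.42% and the 10 highest genes at 9.66%, against 4.66%, 4.03% and 12.6% by TPM.

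Smooth muscle genes were the most abundant cell type list. All 15 members exceeded 1 TPM in both pups, their median mean level was 1964 TPM, and together they took 8.13% of TPM in pup 1 and 7.38% in pup 2. Actg2, the enteric smooth muscle actin, on chromosome 6 from 83512905 to 83536265 (mm10), had the highest mean of the nuclear protein-coding genes at 26640 ± 1399 TPM, although in pup 2 it was below Hba-a2, at 25651 against 26610 TPM. Acta2, the vascular-type smooth muscle actin, reached 16465 ± 1138 TPM, Tpm2 reached 9480 ± 1241 TPM and Myl9 reached 7191 ± 192 TPM. Among receptors and channels of contraction, 11 of 12 were expressed. P2rx1, the ATP-gated channel of detrusor muscle, was far above the rest at 399 ± 12.4 TPM, followed by Kcnmb1 at 17.8 ± 2.84 TPM, Gucy1a1 at 14.2 ± 1.75 TPM and Kcnma1 at 13.1 ± 0.544 TPM. Ryr2, the cardiac-type calcium release channel, stayed below 1 TPM in both pups, at 0.33 and 0.26 TPM.

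Several genes best known from skeletal muscle were also high, while others of the same list were far lower. Acta1, the skeletal alpha-actin, was at 6975 ± 435 TPM, creatine kinase Ckm at 628 ± 40.0 TPM, and the fast troponins Tnnt3 and Tnnc2 at 548 ± 168 and 365 ± 44.1 TPM. In the same list the perinatal myosin Myh8 had 26.5 and 15.9 TPM in pup 1 and pup 2 and the fast troponin Tnni2 15.2 and 10.6 TPM. The fast myosin light chains Mylpf and Myl1 had 2.42 and 2.72 TPM in pup 1 and 1.64 and 0.86 TPM in pup 2, and the muscle regulator Myog had 0 counts in both pups. Of the 12 members, 8 exceeded 1 TPM in both pups.

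Urothelial genes, from the lining epithelium of the bladder, were expressed at high and similar levels in both pups. All 11 genes of the superficial urothelium list were detected, with a median of 299 TPM. The uroplakin Upk3a, a component of the apical membrane plaques, was at 2040 ± 16.1 TPM, Upk1b at 1533 ± 123 TPM, Upk1a at 1442 ± 41.9 TPM and Psca at 1443 ± 48.2 TPM. Genes shared among epithelia were all detected, led by the keratins Krt18 at 1484 ± 176 TPM, Krt8 at 1344 ± 198 TPM, Krt19 at 727 ± 44.3 TPM and Krt7 at 583 ± 42.6 TPM. Of the basal urothelium list, 10 of 12 genes were detected, with Krt15 at 705 ± 16.2 TPM, Krt5 at 222 ± 6.67 TPM, Krt14 at 205 and 220 TPM in pup 1 and pup 2, and the integrin Itga6 at 19.8 ± 1.90 TPM. The desmosomal cadherins Dsc3 and Dsg3 were below 1 TPM in both pups, on 17 and 23 counts and on 5 and 3 counts. Squamous epithelium genes were mostly low, with 5 of 10 detected, but the cornified envelope gene Sprr1a reached 3426 ± 99.6 TPM and Ivl reached 129 ± 6.92 TPM. Krt10 was at 3.88 ± 0.233 TPM and Krt6a at 2.96 ± 1.73 TPM.

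Genes of the connective tissue lay between smooth muscle and superficial urothelium by list median. All 16 members of the fibroblast and matrix list were detected with a median of 355 TPM, led by the collagens Col3a1 at 3480 ± 241 TPM, Col1a1 at 2910 ± 425 TPM and Col1a2 at 1516 ± 161 TPM and by decorin, Dcn, at 1180 ± 82.3 TPM. All 12 endothelial genes were detected at a lower median of 11.4 TPM, among them Egfl7 at 43.6 ± 8.40 TPM, Cldn5 at 28.2 ± 5.10 TPM, Esam at 27.7 ± 3.19 TPM and Pecam1 at 25.9 ± 0.933 TPM. All 8 pericyte genes were detected with a median of 13.1 TPM. The highest were Ndufa4l2 at 275 ± 70.1 TPM, Rgs5 at 30.4 ± 3.34 TPM, Cspg4 at 17.8 ± 0.877 TPM and Kcnj8 at 16.5 ± 1.04 TPM. Of the lymphatic list, Pdpn at 144 ± 16.2 TPM, Lyve1 at 18.9 ± 4.84 TPM and Ccl21a at 4.94 ± 2.47 TPM were detected, whereas Flt4 and Prox1 were below 1 TPM. All 6 mesothelial genes were detected, led by Upk3b at 171 ± 19.2 TPM, Msln at 114 and 131 TPM in pup 1 and pup 2, Nkain4 at 67.0 ± 5.27 TPM and Gpm6a at 17.0 ± 2.56 TPM.

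Nerve genes were detected at low level except Uchl1. In the Schwann cell list 6 of 8 genes passed 1 TPM in both pups, with Fabp7 at 11.7 ± 7.28 TPM and Erbb3 at 6.21 ± 0.728 TPM among them. In the neuron list 4 of 10 did, namely Uchl1 at 211 ± 19.3 TPM, Stmn2 at 8.30 ± 0.594 TPM, Prph at 1.80 ± 0.134 TPM and Tubb3 at 1.11 ± 0.0354 TPM. Of the adipocyte list, Fabp4 at 757 ± 101 TPM, Pnpla2 at 51.6 ± 2.02 TPM and Lpl at 16.3 ± 3.49 TPM were detected and 7 of 10 genes were below 1 TPM in both pups.

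**Figure D1:**
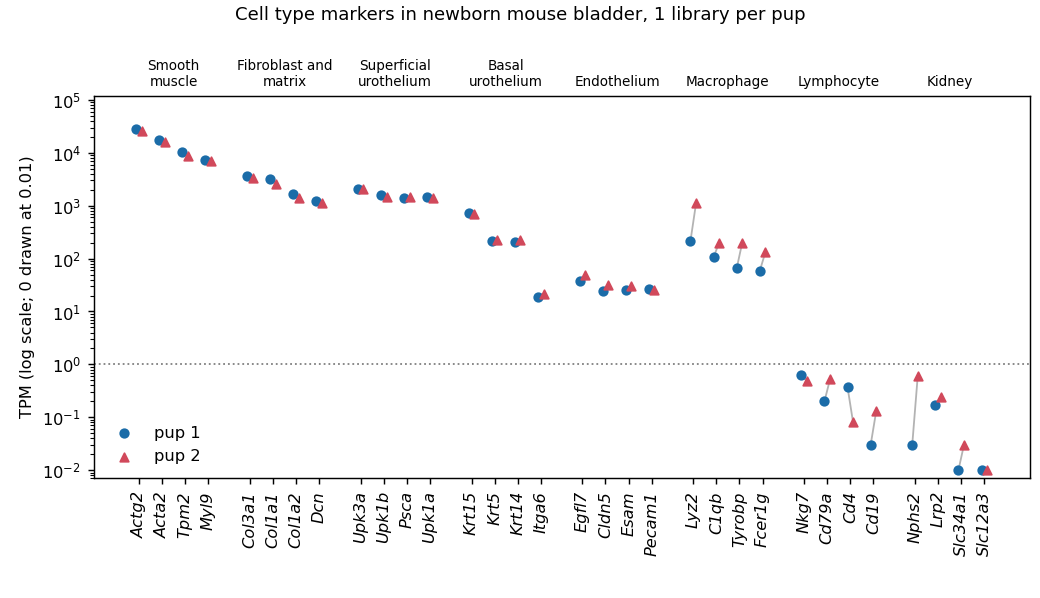
TPM on a log axis of the 4 members with the highest mean in each of 8 cell type lists, with a circle for pup 1 and a triangle for pup 2; the dotted line marks 1 TPM and a value of 0 is drawn at 0.01. Smooth muscle genes reach 26640 TPM on average, macrophage genes are higher in pup 2, and lymphocyte and kidney genes lie below 1 TPM.

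Immune and blood genes differed by type. All 11 macrophage genes were detected with a median of 83.1 TPM, including the lysozyme Lyz2 at 661 ± 629 TPM, C1qb at 152 ± 64.6 TPM, Tyrobp at 132 ± 95.1 TPM and Fcer1g at 94.7 ± 51.2 TPM. All 6 mast cell genes were detected, led by the tryptase Tpsb2 at 85.7 ± 66.7 TPM and the chymase Cma1 at 46.6 ± 21.6 TPM, with the protease Cpa3 at 24.2 ± 0.106 TPM and Kit at 2.66 ± 0.134 TPM. Of the neutrophil list 4 of 7 genes were detected, led by S100a8 at 144 ± 169 TPM and S100a9 at 57.3 ± 68.5 TPM. None of the 8 lymphocyte genes reached 1 TPM in both pups, the highest being Nkg7 at 0.56 ± 0.113 TPM. Adult globins were high, with Hba-a2 at 18004 ± 12171 TPM and Hbb-bs at 11404 ± 6816 TPM, while the embryonic globins Hbb-y and Hba-x stayed at 1.82 ± 1.65 and 1.57 ± 1.14 TPM. Markers of kidney, gut and prostate were mostly below 1 TPM: no kidney gene reached 1 TPM in both pups, and only Lgals4 of the gut epithelium list at 8.10 ± 1.11 TPM and Hoxb13 of the prostate list at 1.64 ± 0.0636 TPM did so. The kidney gene Umod had 0 counts in both pups. Of the liver list 5 of 7 genes passed, the highest being Apoa1 at 12.9 ± 11.3 TPM, Apoa2 at 10.7 ± 10.3 TPM and Alb at 9.67 ± 8.54 TPM.

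Growth and patterning genes were widely expressed. Of 14 imprinted genes 13 were detected, with Gnas at 1192 ± 189 TPM, the fetal growth factor Igf2 at 494 ± 46.6 TPM, Meg3 at 252 ± 1.22 TPM and Dlk1 at 181 ± 9.83 TPM. All 19 proliferation genes were detected with a median of 34.6 TPM, led by Cdk1 at 94.1 ± 18.1 TPM and Pcna at 82.0 ± 13.9 TPM. Of the hedgehog list 9 of 10 were detected, including Foxf1 at 79.9 ± 1.65 TPM, Bmp4 at 52.7 ± 2.52 TPM, Hhip at 21.3 ± 1.71 TPM and Smo at 15.4 ± 0.990 TPM. Of the retinoid list 10 of 14 were detected, including Dhrs3 at 158 ± 4.08 TPM and the retinoic acid synthesising enzyme Aldh1a2 at 40.0 ± 3.24 TPM. Among Hox genes, 5 of 11 in the a cluster, 4 of 10 in the b cluster, 0 of 9 in the c cluster and 6 of 9 in the d cluster were detected, and Hoxa10 was the highest at 79.7 ± 15.3 TPM, followed by Hoxa11 at 17.0 ± 2.11 TPM. The glucocorticoid receptor Nr3c1 was at 37.9 ± 3.14 TPM, whereas Esr1 was at 0.675 ± 0.247 TPM.

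Stress and hypoxia lists were detected nearly in full and the histone list in part. All mitochondrial genes except those of transfer RNAs were detected. All 7 heat shock genes were detected, led by Hspa8 at 1412 ± 157 TPM and Hspb1 at 1189 ± 193 TPM, and so were all 11 hypoxia genes, led by Ldha at 1049 ± 45.7 TPM and Pgk1 at 192 ± 22.7 TPM. Of 14 immediate early genes 13 were detected, with Ier3 at 146 ± 0.969 TPM and Junb at 75.7 and 87.3 TPM in pup 1 and pup 2, and of 10 interferon genes 9 were, with Bst2 at 48.8 ± 7.04 TPM. Ribosomal protein genes were led by Rpl41 at 3002 ± 159 TPM and Rps19 at 1681 ± 211 TPM. Of 37 mitochondrial genes 15 were at 1 TPM or more in both pups, led by mt-Atp6 at 10105 ± 289 TPM. The other 22 were transfer RNA genes, each with 0 counts in both pups. Transfer RNAs are shorter than the size range of the libraries, so these counts cannot tell whether they were expressed. The mitochondrial gene mt-Co3, at 2754 TPM, shared reads with its nuclear copy Gm28437, at 12104 TPM, and its posterior SD reached 196% of its count. Its rank and the mitochondrial share are therefore uncertain. Of 64 replication-dependent histone genes 43 were detected, with Hist1h2ap at 801 ± 220 TPM. Malat1 reached 4389 ± 219 TPM, and the signal recognition particle RNAs Rn7s1 and Rn7s2 shared reads and were each assigned 13870 TPM. Y-linked genes were detected in both pups, with Eif2s3y at 52.0 ± 4.21 TPM, Ddx3y at 34.2 ± 5.42 TPM, Uty at 8.80 ± 0.424 TPM and Kdm5d at 5.94 ± 0.375 TPM, and Xist had 6 and 2 counts and Tsix 5 and 1. By these genes both pups were male. Over the 41 fixed lists, 18 had a median of at least 10 TPM.

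Littermates were close for most genes. Of 12733 genes with a mean expected count of at least 100, 76.7% lay within 1.2-fold and 95.1% within 1.5-fold between the pups after TMM scaling. The log2 ratio of pup 2 over pup 1 had an SD of 0.37 against 0.09 from counting alone, which leaves a coefficient of variation of 17.7%, or 9.59% by the median absolute deviation. Across the 13834 genes detected in both pups, log2 TPM had a Pearson correlation of 0.985 and TPM a Spearman correlation of 0.984, both across genes, which are not independent replicates. The spread was largest at low depth: in genes with 100 to 300 mean counts the robust coefficient of variation was 14.1%, in those with 3000 to 10000 it was 7.92%, and at 10000 or more it was 8.48%. The 2 libraries therefore differed by more than counting noise, and 52.3% of genes had a counting interval that excluded equal levels. These intervals cover counting error only, and animal, dissection and library are not separable with 1 library per pup.

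**Figure D2:**
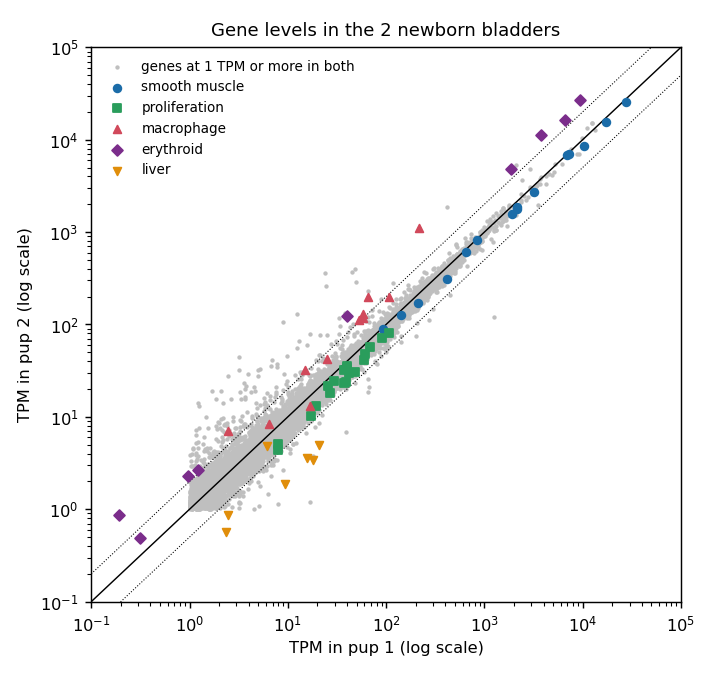
TPM of each gene in pup 1 and in pup 2 on log axes, in grey for genes at 1 TPM or more in both pups and coloured for 5 gene lists with values above 0.1; the solid line marks equal levels and the dotted lines 2-fold differences. Erythroid and macrophage genes lie mostly above the line, with medians of 2.73-fold and 2.26-fold higher in pup 2, and liver genes below it.

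Blood and innate immune lists had medians higher in pup 2. The erythroid list was 2.73-fold higher by its median, with 9 of 9 tested members higher: the globins Hba-a2, Hba-a1, Hbb-bt and Hbb-bs had log2 ratios of 1.58, 1.57, 1.45 and 1.33 and the haem synthesis enzyme Alas2 had 1.66. The macrophage list was 2.26-fold higher, with 10 of 11 members higher and 7 of them by at least 2-fold. Lyz2 had a log2 ratio of 2.43 (95% interval 2.40 to 2.47), Tyrobp was 3.24-fold higher, Ptprc 2.97-fold, Csf1r, the receptor for macrophage colony-stimulating factor, 2.28-fold, and the complement genes C1qc and C1qa 2.26-fold and 2.15-fold. The mannose receptor Mrc1 was the exception, with a log2 ratio of -0.47. The neutrophil list had a median of 2.22, which was 1.57 with 1 added to TPM and 3.58 for members with at least 100 counts. In it, 4 of 5 tested members were higher by at least 2-fold, with S100a9 12.6-fold and S100a8 11.3-fold higher, Ngp at a log2 ratio of 2.22 and Mpo at -0.55. The mast cell list was 1.62-fold higher by its median (log2 ratio 0.70, or 0.31 with 1 added to TPM), with Tpsb2 at 1.87 and Cma1 at 1.06 but Cpa3 at 0.09, and the interferon list was 1.30-fold higher, with Rsad2 at 1.12 and Isg15 at 1.07 but 3 of 9 members lower, among them Ifit1 at -0.57 and Ifit3 at -0.54. The embryonic globins Hbb-y and Hba-x had log2 ratios of 2.27 (11 counts in pup 1 and 40 in pup 2) and 1.49 (16 and 34 counts), and their median of 1.88 became 1.10 with 1 added to TPM.

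Liver-type and cell cycle genes were lower in pup 2. The liver list was 4.02-fold lower by its median (log2 ratio -2.01), with 7 of 7 members lower and 6 of them by at least 2-fold. Alb had 914 counts in pup 1 and 169 in pup 2, Afp 561 and 90, and Apoa1 585 and 110, while Ttr had a log2 ratio of -0.26. The proliferation list had a median of -0.44, with 19 of 19 members lower and none by 2-fold, from Bub1 at -0.78, Top2a at -0.69 and Ccna2 at -0.66 to Ccnb2 at -0.09. The skeletal muscle list had a median of -0.35, with Myl1 at -1.27, Myh8 at -0.66 and Tnnt3 at -0.54 but Acta1 and Ckm at -0.05. The fast myosin Myh2, outside the list and chosen after its values were seen, had -1.22 on 3214 and 1041 counts. The Hox list had a median of -0.15.

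Lists of the main bladder tissues differed little. The medians were -0.09 for smooth muscle, -0.05 for contraction receptors and channels, -0.08 for superficial urothelium, -0.10 for shared epithelium, -0.13 for fibroblast and matrix, -0.01 for pericytes, -0.05 for mesothelium and 0.11 for endothelium, and no member of these 8 lists was 2-fold apart. The muscarinic receptor Chrm2 had the largest difference among the contraction genes, at -0.71. Basal urothelium had a median of 0.17, with 10 of 11 tested members higher in pup 2. Other lists within the central 95% of random lists were squamous epithelium at -0.03, lymphatic endothelium at 0.15, Schwann cell at 0.28, neuron at 0.23, adipocyte at 0.14, gut epithelium at 0.43, imprinted genes at -0.10, heat shock at -0.14, hypoxia at -0.13, hedgehog at 0.02, retinoid at 0.13, Y-linked at -0.13, mitochondrial genome at -0.01 and histones at -0.07. At a mean count of at least 20, the members of these lists 2-fold higher in pup 2 were Fabp7 at 2.71-fold, Krt6a at 2.54-fold, Crabp2 at 2.39-fold, Ccl21a at 2.22-fold and 2 histone genes, and 1 histone gene was 2-fold lower.

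Each list median was placed among 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. Of 37 lists with at least 2 members at a mean count of 20 or more, 15 lay outside the central 95%, against 1.85 expected by chance for independent genes. Of these 15 lists, 11 were higher in pup 2 and 4 lower. Percentiles were 100 for macrophage, neutrophil, mast cell and erythroid, 0 for liver and proliferation, 0.02 for skeletal muscle, 99.9 for interferon, 98.6 for embryonic globin, 99.1 for basal urothelium and 1.34 for Hox genes. The remaining 4 lists above the range were immediate early genes at a median of 0.15, structural RNA at 0.36, ribosomal proteins at 0.10 and steroid receptors at 0.62. Steroid receptors lay inside the range under 3 of 9 alternative settings, with a lowest median of 0.20. Settings that only rescale the libraries cannot change a list's place. The ribosomal protein list also holds kinases of ribosomal protein S6, and without them its median was 0.10 as well. Lymphocyte, kidney, prostate and X inactivation lists had fewer than 2 members with enough counts.

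**Figure D3:**
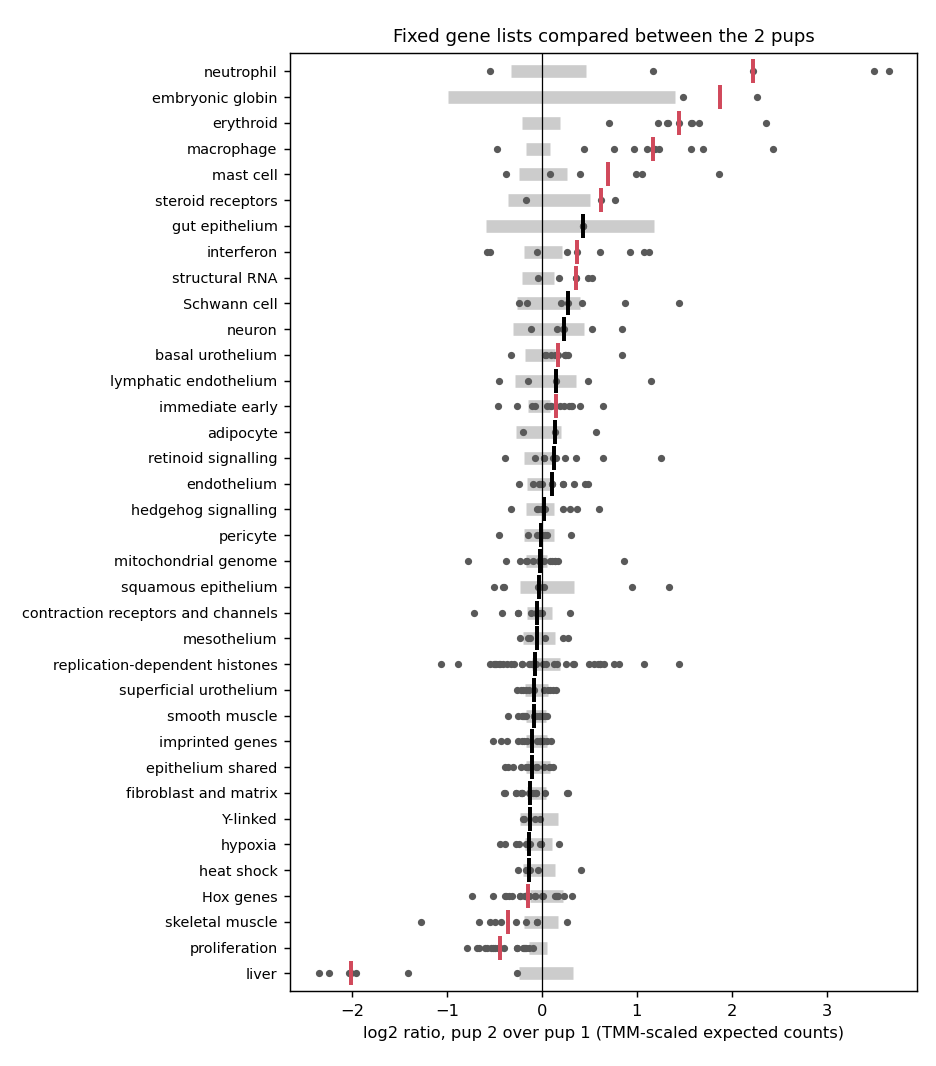
Log2 ratio of pup 2 over pup 1 for the members (dots) of 36 fixed gene lists, ordered by their median (vertical bar, red where it lies outside the central 95% of 10000 matched random lists, grey band). Neutrophil, erythroid and macrophage medians are at 2.22, 1.45 and 1.18, and the liver median is at -2.01.

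Single genes 2-fold apart were few and mostly higher in pup 2. Of the 12733 genes, 252 (1.98%) differed by at least 2-fold, 216 higher and 36 lower in pup 2, and 21 and 5 of these belonged to a fixed list. Among protein-coding genes the largest differences with well assigned reads were those of the cytokine Osm, on chromosome 11 from 4236420 to 4241026 (mm10), with 16 counts in pup 1 and 461 in pup 2 (log2 ratio 5.25, 95% interval 4.54 to 6.07), and of Retnlg, a resistin-like gene of neutrophils, at 4.46. Arg1, which encodes arginase, followed at 4.02 with 984 and 12023 counts, the acute phase gene Saa3 at 3.87 and the myeloid receptor Trem1 at 3.69. Downward, the fibrinogen chains Fga and Fgg had -2.69 and -2.46, Apoa2 -2.35, Afp -2.24, fetuin Ahsg -2.19, Serpina1e -2.07 and the kininogen Kng1 -2.04, all genes of plasma proteins, on 23 to 124 counts in pup 2.

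Reads shared between near-identical genes set several values. Tom1 had 0 counts in pup 1 and 307 in pup 2, but its posterior SD exceeded its count, so its ratio is uncertain. Tmem254a had a log2 ratio of -4.03, yet summed with its copies Tmem254b and Tmem254c the ratio was -0.04 (95% interval -0.12 to 0.04). Xlr3b was at 4.45, and its sum with Xlr3a and Xlr3c remained at 3.85. The mitochondrial gene mt-Co3 was at -0.78, and its sum with the nuclear copy Gm28437 was at 0.15. The copies beside Tmem254a, Xlr3b and mt-Co3, and mt-Co3 itself, were chosen after their values were seen. Leaving out genes whose posterior SD exceeded 10% of the count in either pup, a step added after seeing the data, left 231 genes 2-fold apart, 208 higher and 23 lower in pup 2.

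Spike-in RNAs gave little information on library noise. Of 97 spike-in entries, 20 were detected in pup 1 and 22 in pup 2, on 363 and 275 counts, or 8.32 and 8.44 ppm. Only 4 had a mean count of at least 20, with an SD of the log2 ratio of 0.37 against 0.28 from counting alone. The 1024 mouse genes in the same count range had an SD of 0.71. The spike-in total gave a log2 ratio of 0.00 (95% interval -0.23 to 0.23) after TMM scaling.

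Isoform use was largely shared between the pups. In 5605 genes with at least 10 TPM in both pups and at least 2 annotated transcripts, the leading transcript was the same in 5243, or 93.5% (exact 95% interval 92.9 to 94.2). This interval runs over genes, which are not independent, and covers no spread between animals or libraries. The share of the leading transcript moved by a median of 2.77 percentage points, and by over 10 points in 11.3% of genes. Among list genes with a mean count of at least 500, the largest moves were those of Rps6ka1 and Adm. The leading transcript of the kinase Rps6ka1 took 92.2% of the gene in pup 1 and 62.4% in pup 2, or 79% and 53% by posterior means. For Adm the transcript leading in pup 1 took 77.0% and 47.6%, and another transcript led in pup 2 at 51.7%. Mrc1 had 84.7% and 67.1%, Rara 47.0% and 61.9%, and Cenpf 39.2% and 53.7%. For Hba-a1 the leading transcript, at 71.3% and 82.9%, is annotated as a retained intron. The posterior SD of the Adm transcript leading in pup 1 was 28.9% of its count in pup 1 and 40.2% in pup 2, so its shift is uncertain. For the Rps6ka1 transcript that SD was 6.54% and 15.7%, so the size of its shift is uncertain as well.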

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

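With 2 samples no sample can be tested for standing apart from its group. Counts were present in entries that no comparison used: those with a numeric identifier instead of a gene name held 32.4 expected counts in pup 1 and 32 in pup 2, above the 3 counts that a count of 0 allows. They lay on 4 entries in pup 1 and 3 in pup 2, with 2 entries in common, and made up 0.742 and 0.983 ppm of the counts.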

How the results depend on the processing

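The number of genes 2-fold apart and the spread depended mainly on the count filter. With a mean count of at least 10, 894 genes were 2-fold apart (632 higher and 262 lower in pup 2), with at least 500, 84 (74 and 10), and with no filter and 0.5 added, 5156 (2888 and 2268), against 252 (216 and 36). These follow from the construction, which adds or drops genes of few counts. All 252 were among the genes of the looser filters. Leaving out uncertain counts, chosen after seeing the data, kept 12568 of 12733 genes. It left 23 of 36 lower genes and 208 of 216 higher genes, so a larger part of the lower genes rested on uncertain read assignment. Leaving out blood, immune and liver lists, also chosen later, left 230 in all. This step kept 12704 of 12733 genes, and unlisted genes such as Retnlg, Fga and Fgg stayed in. It therefore cannot tell what part of the 252 came from blood, immune or liver RNA. The SD of the log2 ratio was 0.54 and 0.28 with the filters at 10 and 500, 0.32 with TPM + 1 and 0.36 with posterior means, against 0.37; adding 1 shrinks ratios of low genes by construction, and the cause of the last was not tested. By expected counts the mitochondrial share was 2.62% and that of the 10 highest genes 9.66%, since counts are not divided by length. The leading transcript was the same in 90.4% of genes at 1 TPM and 96.2% at 50 TPM.

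All other alternatives left the counts of expressed genes (9886 to 16846), of lists at 10 TPM (15 to 21) and of lists outside the random range (13 to 17) within 1.5 times the main value, and 13 of 15 such lists stayed outside with their sign under all 9 alternatives. Embryonic globins did so under the 8 that gave a value, with no member at 100 counts, and steroid receptors under 6 of 9. Their size held less well: over these alternatives the median log2 ratio ran from 1.57 to 3.58 for neutrophil, 0.31 to 0.73 for mast cell, 1.10 to 1.90 for embryonic globin, 0.09 to 0.22 for basal urothelium, 0.06 to 0.19 for immediate early genes, 0.02 to 0.15 for ribosomal proteins and 0.20 to 0.64 for steroid receptors, each lowest with TPM + 1, which by construction shrinks low genes and here shifted the median gene by -0.07. Scaling by DESeq2, total count or spike-ins moved the median gene by at most 0.02. It shifts every gene by the same amount, so these alternatives were bound to leave each list's place among random lists unchanged. Only the other alternatives could test that place. Of 1253 alternative log2 ratios of 179 named genes, 1240 kept their call, 12 were weaker and 1 stronger. The call is whether a gene was 2-fold apart. No gene called 2-fold apart changed sign, but a change of sign in a gene closer than 2-fold counted as kept. Such changes occurred with TPM ratios: Krt7 had a log2 ratio of 0.08, yet 613 TPM in pup 1 and 553 TPM in pup 2. Levels held less well: 243 of 884 alternative mean levels of named genes and 79 of 212 of list medians moved by more than the SD between pups, mostly in FPKM or after rescaling to nuclear protein-coding genes. Each pup alone is among these alternatives, and with 2 pups its gene level lies within that SD of the mean by construction. These shares therefore understate how often levels moved under the settings that could move them. Single pups gave a globin share of 2.17% and 5.90%, against 4.03%. Results between pups need both, so neither could be left out. No spike-in reached a mean count of 100, so that setting gave no value. Depth limits genes under 100 counts, where 3 counts bound what can be detected.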

Other observations

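The tests in this part, both added gene lists in it, and the genes Apoe, Trf and Ftl1 were chosen after the results were seen. Besides cell type markers, genes of inflammation were higher in pup 2. Of 16 inflammatory mediators with a mean count of at least 20, 15 were higher in pup 2 and 12 by at least 2-fold, with a median log2 ratio of 2.28 (1.75 to 3.05 over 9 alternatives). Arg1 was 16.2-fold higher, the chemokine Ccl6 had 3.13, osteopontin Spp1 2.98, the endotoxin co-receptor Cd14 2.44, the haem-degrading enzyme Hmox1 1.91 and Ccl2 1.25, whereas Nos2 had -0.23 and Ptgs2 0.30. Among single genes, Apoe was at 416 TPM in pup 1 and 1867 TPM in pup 2, transferrin Trf had a log2 ratio of 1.47 and ferritin Ftl1 0.79.

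Genes of cholesterol synthesis were lower in pup 2. All 24 members of the list were lower, 6 by at least 2-fold, with a median log2 ratio of -0.84. The synthase Hmgcs1 had -1.18, Idi1 -1.35, Hsd17b7 -1.32, Fdps -1.03 and squalene epoxidase Sqle -0.89. The smallest difference was that of Ebp at -0.12. Both lists were picked from these libraries and are no independent evidence of direction.

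Macrophage and neutrophil genes were higher in pup 2. More blood of the same makeup would raise no gene above the erythroid genes, and the 6 of these with a mean count of at least 100 had upper interval bounds of at most 1.73, while Epb42, with 9 and 35 counts, had 2.36 (95% interval 1.28 to 3.61). Of 5 tested neutrophil genes, 3 (S100a8, S100a9 and, narrowly, Ngp) had a lower bound above 1.73, but none had one above the 3.61 of Epb42. The lower bounds of S100a9 and S100a8 were 3.37 and 3.29. With Epb42 set aside for its few counts, this argues against such blood as the whole source of those genes. With Epb42 counted, the question stays open. Of 11 macrophage genes only 1, Lyz2, had a lower bound above 1.73, so for the macrophage list it stays open either way. Carry-over of liver, a blood-forming organ at birth, would raise liver genes, whose median was -2.01. No biological explanation was tested, since the design names no factor that differs between the pups.

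Sterol synthesis genes were lower in pup 2. Dilution by blood and immune RNA would lower tissue lists alike, and the sterol median lay at -0.76 relative to smooth muscle. The sterol list was picked after its values were seen, so such a gap was given by the choice, and no conclusion on dilution is drawn. After removal of trends on GC content and length the median was -0.83. That correction had an SD of only 0.08 over genes, so the trends found were small beside the sterol difference. Carry-over of liver into pup 1 would bring more plasma protein RNA than sterol RNA, whereas the sterol list had 25.0 times the excess TPM of the liver list in pup 1. For the genes of this picked list, these values argue against GC content and length, and against liver carry-over, as the whole cause. They reach no further than these genes, since the size of the difference was given by the choice. What else lowered them is left open, and no biological explanation was tested.

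Skeletal-type contractile genes Acta1, Ckm, Tnnt3 and Tnnc2 were high in both pups. Reads shared with related genes would give uncertain counts, but the highest posterior SD was 0.0330% of the count, which argues against them as the source. Carried-over skeletal muscle would bring its other abundant transcripts, but Tnni2, the partner of Tnnt3 and Tnnc2 in the fast troponin complex, reached at most 3.85% of the lower of these genes, and the highest of the 8 other members, Myh8, 6.69% and 4.76% of the lowest high gene in pup 1 and pup 2. This argues against carry-over as the whole source, and a small share of it stays open. No biological explanation was tested.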
